A study of Homo sapiens with 12 samples.

How the data were processed

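Gene expression was measured on 12 Affymetrix arrays, each with 54675 probe sets. The samples were 2 human T-cell acute lymphoblastic leukaemia lines, KOPT-K1 and HPB-ALL, treated with the peptide SAHM1 at 20 µM or with its vehicle DMSO for 24 hours. Per the labels and the design text, each of the 4 groups held 3 cultures, and each culture gave 1 array, so p-values measure the spread between cultures handled in the same experiment.

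The submitters' processing notes name RMA, which corrects background, normalizes between arrays and summarises probes on a log scale. Its version, and the annotation it was run with, are not given in the sources used here. The deposited values are linear ratios, which the file itself shows: in 54675 of 54675 probe sets the mean of the 3 DMSO arrays of KOPT-K1 was 1 within a tolerance of 1e-06, and the same held in 54675 probe sets for HPB-ALL. Every deposited value is thus a ratio to the mean of the same line's DMSO arrays, and the values ran from 0.0827 to 6.98. Signal levels, and the difference between the lines in DMSO, are lost in this scale. Depth has no counterpart on arrays: their number limits the precision. No pair of arrays held identical values, and 0 sample columns were left unused.

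The ratios were turned into log2 values with no pseudocount. Symbols came from the platform annotation supplied with the series: 41097 probe sets carried 1 symbol, 1801 carried several, 11777 were not listed there, and 62 probe sets of the array were controls. Of the probe sets with 1 symbol, 41043 were matched by gene identifier to a current symbol table, and 0 symbols changed. Probe sets with several symbols were not used to name genes. The log2 values of all probe sets with the same single symbol were averaged, which gave 19775 genes, 9252 of them from 1 probe set and the others from up to 20. For the NOTCH target genes named, the fixed NOTCH genes and the genes with the largest changes, probe sets that differed in call or widely in size are given beside the gene. Probe sets of other list members were not compared singly.

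The tests, the samples in each fit, the gene lists and the rule for named genes were set before the data were examined. The plan had assumed levels, and the ratio scale forced departures from it. A filter on low values and the choice of the brightest probe set per gene need levels, so no filter was applied and the mean of all probe sets was used, both of which had been listed as alternatives. The planned comparison of the lines in DMSO could not be made.

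Linear models were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) to all 12 arrays with the 4 groups as terms, which left 8 residual degrees of freedom, or 12.6 after moderation. The 4 contrasts were SAHM1 against DMSO in KOPT-K1, the same in HPB-ALL, the mean of both, and the HPB-ALL response minus the KOPT-K1 response. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called changed. The same steps were tested on simulated data for 19775 genes. The noise was drawn independently for each gene, with the spread of that gene within the real groups. It held no signal shared across an array or between genes, so the recovery and false calls below leave such signal out. At a log2 change of 0.5, 81% of changed genes were recovered in KOPT-K1, 78% in HPB-ALL and 91% for the mean of both lines. At a log2 change of 1 the shares were 97%, 100% and 100%, and 13, 11 and 9 of 19558 unchanged genes were called.

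The 19 gene lists, compiled from general knowledge, were NOTCH target genes, NOTCH pathway components, MYC-driven ribosome biogenesis, G1/S and DNA replication, G2/M and mitosis, p53 targets and apoptosis, ATF4 and amino acid response, ER unfolded protein response, cholesterol synthesis, interferon-stimulated genes, NF-kB targets, immediate early and T-cell activation, cytosolic heat shock, NRF2 and oxidative stress, glycolysis and hypoxia, mitochondrial respiratory chain, T-lineage and thymocyte genes, B-cell, myeloid and erythroid markers, and replication-dependent histones. They held 461 entries, of which 414 were measured. Each list was tested against the other genes with limma's camera, at a preset correlation between genes of 0.01, adjusted over the 19 lists within a contrast, and again with a correlation estimated per list. Members were also counted after adjustment over the list alone. Each list's mean log2 value per array was its score, compared by an exact two-sided permutation of the treatment labels within lines. There were 400 relabellings over both lines, with a smallest p of 0.005, and 20 within a line, where no p can be under 0.10.

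Named genes were a fixed set of NOTCH genes (HES1, HEY1, DTX1, NRARP, MYC, NOTCH1, NOTCH3, PTCRA, RBPJ, MAML1), the 8 largest rises and 8 largest falls among called genes whose SAHM1 arrays all lay beyond the DMSO arrays (in each line and for the mean), up to 4 members per list and comparison with the smallest p, and the 5 largest differences between lines in each direction. Other genes are said to be chosen after their values were seen.

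Replicate numbers were not used as a block, since the labels do not say that a number marks a shared day or culture. Alternatives tried were quantile normalization, a shift of each array to the same median, leaving out probe sets with the suffix _x_at or _s_at, probe sets tested singly, a trended robust variance, array weights, the replicate number as a block, a minimum log2 difference of 1, fits to the 6 arrays of a line, estimated correlations and fry for the lists, and leaving out each array in turn. The mean signal of the 18 hybridization spike probe sets and of the 3 probe sets for 18S ribosomal RNA on each array were added as covariates after the data had been seen. Leaving out probe sets with the suffix _x_at or _s_at had been planned with the brightest probe set per gene, and was run with the mean instead once the ratio scale was known.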

Results

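The data cover 12 arrays of KOPT-K1 and HPB-ALL, 2 human T-cell acute lymphoblastic leukaemia lines that both depend on activated NOTCH1. Each line was cultured for 24 hours with DMSO or with 20 µM SAHM1, with 3 cultures per condition. SAHM1 is a hydrocarbon-stapled alpha-helical peptide taken from mastermind-like, a co-activator that binds the NOTCH transcription complex, and it was made to block that complex. The question was which genes change with SAHM1, with NOTCH target genes as the first interest. Changes are given as log2 differences ± the standard error from limma, with n = 3 arrays per group, and list tests as camera's adjusted p. The median standard error of a gene's change within a line was 0.08, a precision limited by the number of arrays.

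NOTCH target genes fell in both lines. HES4, a transcriptional repressor of the hairy and enhancer of split family, changed by -1.24 ± 0.10 in KOPT-K1 and -1.24 ± 0.10 in HPB-ALL. These are falls of 2.37-fold and 2.35-fold. DTX1, a ubiquitin ligase that acts on NOTCH, changed by -0.86 ± 0.09 and -1.30 ± 0.09. MYC changed by -0.69 ± 0.07 and -0.65 ± 0.07, and the repressor HES1 by -0.69 ± 0.05 and -0.59 ± 0.05. For HES1, 2 of 3 probe sets were called in each line, both with the suffix _s_at. Single probe sets ranged from -1.09 to -0.04 in KOPT-K1 and from -1.01 to -0.08 in HPB-ALL. The smallest change in each line was that of the set without this suffix. HES4 rested on 1 probe set with the suffix _x_at and MYC on 1 with the suffix _s_at. Neither gene was thus measured in the setting that leaves such probe sets out. RHOU and SHQ1, chosen after their values were seen, fell in both lines. RHOU fell by 0.82 ± 0.11 in KOPT-K1 and by 0.62 ± 0.11 in HPB-ALL, with 1 of its 2 probe sets called in each line, and 1 of 2 was called for SHQ1 in KOPT-K1. CR2, chosen in the same way, was lower as the mean of 2 probe sets, but these moved in opposite directions in KOPT-K1 (-1.08 and 0.43, both called) and stood at -0.81 and -0.02 in HPB-ALL.

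Of the 21 NOTCH target genes, 11 fell and 0 rose in the mean over both lines, and 12 fell when p was adjusted over the list alone. In KOPT-K1 10 fell and 1 rose (11 and 1 adjusted over the list alone), and in HPB-ALL 8 fell and 0 rose (10 and 0). The list was lower by camera with adjusted p = 1.89e-09 for the mean, 4.81e-05 in KOPT-K1 and 1.47e-07 in HPB-ALL. All 3 calls held with an estimated correlation (adjusted p = 0.0012, 0.0162 and 0.0022). Its score changed by -0.33 in KOPT-K1, -0.31 in HPB-ALL and -0.32 on average. The exact permutation p of the average was 0.005, the smallest that 400 relabellings can give, and 0.0158 after adjustment over the 19 lists. Within each line the exact p was 0.10, the smallest possible with 3 arrays against 3. HEY1 was the member that rose in KOPT-K1 (0.36 ± 0.10, adjusted p = 0.0284), with probe sets at 0.14 and 0.58. Its value in HPB-ALL was -0.28 ± 0.10 (adjusted p = 0.118). NOTCH3 fell in HPB-ALL (-0.34 ± 0.08) with 1 of 2 probe sets called, and was at -0.20 ± 0.08 in KOPT-K1 (adjusted p = 0.0984, probe sets at -0.40 and -0.01). NRARP, NOTCH1 and PTCRA passed the test in neither line, with values between -0.16 and 0.12. Single probe sets ran from -0.13 to 0.25 for NOTCH1 and from -0.17 to 0.43 for PTCRA in KOPT-K1, and from -0.38 to 0.06 for NOTCH1 in HPB-ALL. RBPJ and MAML1, the partners of NOTCH in the complex, were at -0.22 ± 0.07 and 0.06 ± 0.06 in KOPT-K1 and at -0.06 ± 0.07 and 0.01 ± 0.06 in HPB-ALL. None of these 4 values passed the test, but 1 of 3 RBPJ probe sets did in KOPT-K1 (-0.45). The wider list of NOTCH pathway components was not called in any comparison (adjusted p = 0.281 in KOPT-K1 and 0.527 in HPB-ALL). Of its 33 measured members 2 rose and 6 fell in KOPT-K1 (2 and 9 adjusted over the list alone), and 2 rose and 1 fell in HPB-ALL (2 and 1). The proteases ADAM17 (-0.39 ± 0.06) and ADAM10 (-0.38 ± 0.06), which cleave NOTCH receptors, fell in KOPT-K1.

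**Figure D1:**
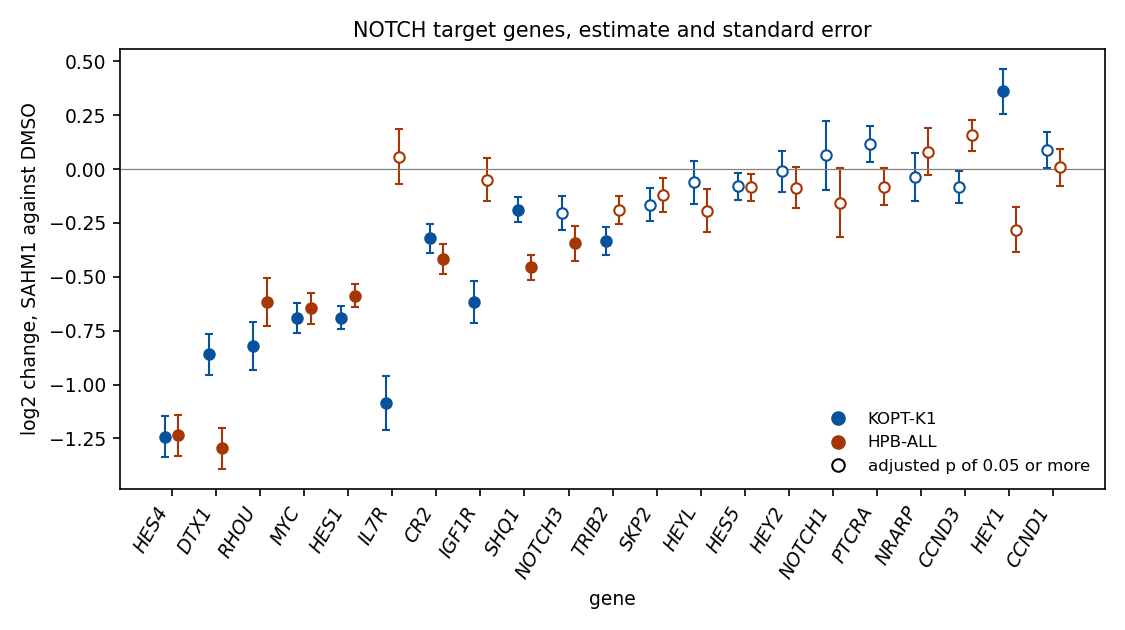
Log2 change with SAHM1 against DMSO for the 21 NOTCH target genes, 1 point per gene and line (blue, KOPT-K1; brown, HPB-ALL), with bars for the standard error and open points for an adjusted p of 0.05 or more. HES4, DTX1, RHOU, MYC and HES1 lie below 0 in both lines, and HEY1 lies at 0.36 in KOPT-K1.

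Averaged over both lines, 2231 of 19775 genes changed, 625 higher and 1606 lower. JUN, a subunit of the AP-1 transcription factor, rose by 1.30 ± 0.07, and the core histone gene H2AC6 by 0.74 ± 0.09. LOC100505915 (0.92 ± 0.08), SRGAP2C (0.68 ± 0.12), SEPTIN7P13 (0.68 ± 0.09), C17orf67 (0.65 ± 0.05), FLRT3 (0.64 ± 0.07) and EPM2A-DT (0.56 ± 0.06) also rose. After HES4 and DTX1, the largest falls that held in every array were in DDIT4 (-0.97 ± 0.06), an inhibitor of mTORC1 signalling, PFKFB3 (-0.94 ± 0.08), which makes the main activator of glycolytic phosphofructokinase. They were followed by BHLHE40 (-0.81 ± 0.06), MIR210HG (-0.81 ± 0.08), the host transcript of a hypoxia-induced microRNA, ELMO1 (-0.79 ± 0.07) and CD300A (-0.79 ± 0.05). CD300A probe sets ran from -1.49 to -0.11 in KOPT-K1 and from -1.20 to -0.04 in HPB-ALL. In HPB-ALL 1 of 2 probe sets was called for BHLHE40 (-0.98, the other at -0.22), MIR210HG (-1.83, the other at -0.43) and FLRT3 (1.47, the other at 0.64). In KOPT-K1 1 of 2 was called for MIR210HG and 0 of 2 for FLRT3, and 2 of 4 for JUN (0.54 to 1.49).

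Glycolysis and hypoxia genes fell in the mean of both lines in 22 of 28 cases (26 adjusted over the list alone, adjusted p = 5.31e-24). Among them were HK2 (-0.77 ± 0.06), the hexokinase of growing cells, BNIP3 (-0.68 ± 0.05) and PDK1 (-0.55 ± 0.05). Genes of MYC-driven ribosome biogenesis fell in 17 of 27 cases (24, adjusted p = 1.39e-15). SRM (-0.66 ± 0.06) and MRTO4 (-0.55 ± 0.06) were examples. G2/M and mitosis genes rose in 20 of 26 cases (22, adjusted p = 1.48e-20). HMMR rose by 0.45 ± 0.04 and CCNB1, the mitotic cyclin, by 0.35 ± 0.04. Cholesterol synthesis rose in 6 of 18 cases (7, adjusted p = 2.42e-05), but its score differed by 0.23 in KOPT-K1 and by -0.01 in HPB-ALL, and the mean of 0.11 had an exact permutation p of 0.065 (adjusted p = 0.121). G1/S and DNA replication fell in 9 of 28 (13, adjusted p = 8.26e-05), with adjusted p = 0.149 with an estimated correlation. Heat shock (3 of 13 lower, 5 adjusted over the list alone), NRF2 (4 of 16, 5) and T-lineage genes (8 of 33 lower and 3 higher, 11 and 3) were called lower at adjusted p = 0.0237, 0.0164 and 0.0164, against adjusted p = 0.164, 0.164 and 0.166 with an estimated correlation. Histones rose in 3 of 13 cases (5, adjusted p = 4.59e-06), with adjusted p = 0.0597 with an estimated correlation. Their score differed by 0.34 (exact permutation p = 0.095), and by 0.12 ± 0.06 with the 18S level as a covariate.

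The ATF4 list was lower in the mean (18 of 24 fell, 18 adjusted over the list alone, adjusted p = 5.38e-17), but it moved in opposite directions in the 2 lines. Its mean score of -0.36 had an exact permutation p of 0.145. The exact test of scores also passed for the mitochondrial respiratory chain (-0.06, adjusted p = 0.0158) and for interferon-stimulated genes (-0.07, adjusted p = 0.0407), which camera did not call for the mean (adjusted p = 0.0802 for each). Over the 4 comparisons camera called 37 of 76 list tests, and 19 of these held with an estimated correlation. They were NOTCH targets, glycolysis and ATF4 in each line and in the mean, and MYC-driven genes and G2/M in HPB-ALL and in the mean. The others were cholesterol synthesis in KOPT-K1 and in the mean, heat shock and histones in HPB-ALL, and ATF4 and G2/M in the difference between lines. With an estimated correlation the adjusted p of these 19 ran from 1.50e-04 to 0.0233, and each was larger than at the preset correlation. The count of 2231 genes became 294 under quantile normalization, 1239 without probe sets of the suffix _x_at or _s_at, and 752 with the 18S level as a covariate.

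In KOPT-K1, genes of the ATF4 and amino acid response fell together: 21 of 24 were lower and 0 higher, also when adjusted over the list alone. Camera gave adjusted p = 1.18e-30, and adjusted p = 0.0013 with an estimated correlation. CHAC1, an enzyme that degrades glutathione, fell 6.26-fold (-2.65 ± 0.13). SLC7A11, the cystine transporter, fell 4.27-fold (-2.09 ± 0.09, probe sets from -2.97 to -0.91), and SESN2, a leucine sensor of the mTORC1 pathway, 3.60-fold (-1.85 ± 0.11). VLDLR (-1.81 ± 0.13), the serine synthesis enzyme PSAT1 (-1.77 ± 0.07) and the transcription factor CEBPB (-1.44 ± 0.06) were also lower. Outside the list, the annexin ANXA3 had the largest fall, 9.86-fold (-3.30 ± 0.17). It was followed by the amino acid transaminase BCAT1 (-2.08 ± 0.06, probe sets from -2.55 to -1.53), the calcium-binding protein S100P (-1.996 ± 0.13) and TM6SF1 (-1.99 ± 0.12). The largest rises were in FRG1BP (1.38 ± 0.13, probe sets at 0.99 and 1.77), ZNF528 (1.34 ± 0.21), PLSCR4 (1.26 ± 0.17), LOC100505915 (1.24 ± 0.11), LINC02504 (1.15 ± 0.17), DSPP (1.10 ± 0.15), MEFV (1.10 ± 0.15) and SH3GL3 (1.00 ± 0.12, probe sets from 0.52 to 1.78 with 2 of 3 called). ZNF528, LINC02504 and MEFV each rested on 1 probe set with the suffix _x_at, and DSPP on 1 with the suffix _s_at.

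Glycolysis and hypoxia genes fell in KOPT-K1 in 11 of 28 cases (14 adjusted over the list alone, adjusted p = 7.89e-08, and adjusted p = 0.0170 with an estimated correlation). VEGFA, the endothelial growth factor, was at -1.10 ± 0.09 and HK2 at -0.89 ± 0.08. Cholesterol synthesis genes rose in 7 of 18 cases (8, adjusted p = 1.05e-06, and adjusted p = 0.0162 with an estimated correlation). HMGCS1 (0.64 ± 0.06) and MSMO1 (0.56 ± 0.06) led them. MYC-driven genes fell in 10 of 27 cases (16, adjusted p = 1.24e-04, and adjusted p = 0.0645 with an estimated correlation). UTP20 was at -0.70 ± 0.13 and WDR43 at -0.68 ± 0.09. G1/S genes fell in 11 of 28 cases (12 lower and 1 higher over the list alone, adjusted p = 0.0017, and adjusted p = 0.213 with an estimated correlation). CDC6 and MCM2, which license replication origins, fell by 0.48 ± 0.06 and by 0.45 ± 0.06. T-lineage genes fell in 12 and rose in 3 of 33 cases (14 and 3, adjusted p = 0.0017, and adjusted p = 0.153 with an estimated correlation). RAG2 was at -0.81 ± 0.11, CD1A at -0.54 ± 0.06 and DNTT at 0.29 ± 0.08. G2/M genes rose in 4 of 26 cases (3, adjusted p = 0.0447, and adjusted p = 0.162 with an estimated correlation), CCNB1 by 0.31 ± 0.06.

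The other lists were not called in KOPT-K1 (adjusted p from 0.101 to 0.918). Members changed in p53 targets (1 up and 6 down of 21, PMAIP1 at -0.63 ± 0.06; adjusted over the list alone 2 and 6), the ER unfolded protein response (0 and 5 of 17, EDEM1 at -0.74 ± 0.06; 1 and 5). They also changed in interferon-stimulated genes (1 and 6 of 24, MX1 at -0.52 ± 0.13; 1 and 7) and NF-kB targets (4 and 0 of 16, TNFAIP3 at 0.46 ± 0.08; 4 and 0). The same counts were 1 and 5 of 20 for immediate early genes (DUSP6 at -0.57 ± 0.06; 1 and 5) and 3 and 1 of 13 for heat shock (DNAJB1 at 0.45 ± 0.07; 3 and 1). They were 0 and 2 of 16 for NRF2 (GCLM at -0.39 ± 0.07; 0 and 2) and 3 and 4 of 22 for the respiratory chain (CYCS at -0.46 ± 0.09; 3 and 4). Markers of B cells, myeloid and erythroid cells had 2 up and 0 down of 14 (MS4A1 at 0.32 ± 0.07; 2 and 0), and histones 2 and 0 of 13 (H2BC12 at 0.35 ± 0.07; 2 and 0). For histones the mean (-0.07) and median (-0.02) were below 0 and the direction of the test was up. In total 3761 genes changed, 1156 higher and 2605 lower, 7 and 51 of them by a log2 difference of at least 1. The 18 hybridization spike probe sets were higher by 0.83 in the SAHM1 arrays of KOPT-K1 (exact permutation p = 0.10). The ACTB probe sets differed between the 5' and the 3' end by -0.17 more than in DMSO (exact permutation p = 0.10). The same measure for GAPDH was at 0.0089 (exact permutation p = 0.80). The count was 136 under quantile normalization, which gives every array the same spread, 2497 without probe sets of the suffix _x_at or _s_at, 3491 with the 18S level as a covariate and 597 with the spike level added.

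In HPB-ALL, G2/M and mitosis genes rose in 21 of 26 cases with 0 lower (23 adjusted over the list alone, adjusted p = 4.76e-27). HMMR rose by 0.79 ± 0.06, the kinetochore motor CENPE by 0.69 ± 0.08 and the phosphatase CDC25C by 0.58 ± 0.07. Glycolysis and hypoxia genes fell in 22 of 28 cases (24, adjusted p = 2.45e-23). PFKFB3 was at -1.28 ± 0.11, ALDOC, an aldolase, at -1.16 ± 0.12 and BNIP3 at -0.98 ± 0.07. The ATF4 list rose, with 17 of 24 higher and 1 lower (19 and 1, adjusted p = 3.08e-16). CHAC1 rose 2.56-fold (1.36 ± 0.13), VLDLR by 1.11 ± 0.13 and SESN2 by 0.88 ± 0.11, while DDIT4 fell (-0.79 ± 0.09). MYC-driven ribosome biogenesis genes fell in 17 of 27 cases (17, adjusted p = 1.53e-14). SRM was at -0.93 ± 0.09 and MRTO4 at -0.66 ± 0.08. With an estimated correlation the adjusted p was 1.50e-04 for G2/M, 8.80e-04 for glycolysis, 0.0025 for ATF4 and 0.0022 for MYC-driven genes. These member counts are without covariates, and with the 18S level as a covariate only 52 genes were called in this line. The scores of G2/M, glycolysis, ATF4 and MYC-driven genes then differed by 0.39, -0.42, 0.46 and -0.29. JUN rose 3.35-fold (1.74 ± 0.10, single probe sets from 0.74 to 2.38). ASS1, which makes argininosuccinate, rose by 1.45 ± 0.12, and TXNIP, a glucose-responsive inhibitor of thioredoxin, by 1.30 ± 0.07.

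The 3 largest rises in HPB-ALL were in the linker histone genes H1-5 (2.69 ± 0.50), H1-3 (2.38 ± 0.52) and H1-4 (2.37 ± 0.47), and H1-2 (1.59 ± 0.30) came after JUN. In the histone list 6 of the 13 measured genes rose with 0 lower (7 adjusted over the list alone, adjusted p = 1.57e-08, and adjusted p = 0.0233 with an estimated correlation). Probe sets for 18S ribosomal RNA were higher by 2.19 in the SAHM1 arrays of HPB-ALL (exact permutation p = 0.10). Within DMSO they stood at 1.05 in replicate 1 against -1.01 and -1.65 in replicates 2 and 3. The histone score on these 3 arrays was 0.29, -0.31 and -0.26. Over all genes, each DMSO array's deviation from another was compared with the SAHM1 response measured against the remaining one. The correlation was 0.29 for replicate 1, -0.19 for replicate 2 and -0.09 for replicate 3. These 3 values add up to 0 by construction, so they are not separate observations. The move with 18S was not confined to histones. MALAT1 and ASPM, chosen after their values were seen, went from 1.18 and 1.17 to 0.20 and 0.36 with the 18S level as a covariate. With the 18S level as a covariate H1-5, H1-3, H1-4 and H1-2 stood at 0.59 ± 0.38, 0.08 ± 0.26, 0.34 ± 0.31 and 0.33 ± 0.23 and passed no test (adjusted p = 0.802, 0.987, 0.902 and 0.826), and the histone score differed by 0.25 ± 0.11, against 0.76 without it. ACTB probe sets differed between the 5' and the 3' end by -0.24 more than in DMSO (exact permutation p = 0.10), and GAPDH probe sets by -0.0123 (exact permutation p = 0.70). Besides DTX1, HES4, PFKFB3 and ALDOC, the largest falls were in the adenylate kinase AK4 (-1.13 ± 0.08, probe sets from -2.35 to -0.35), MIR210HG (-1.13 ± 0.12), LSP1 (-1.07 ± 0.10) and the protease LGMN (-1.05 ± 0.17).

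Heat shock genes fell in HPB-ALL in 5 of 13 cases (5 adjusted over the list alone, adjusted p = 7.30e-06, and adjusted p = 0.0233 with an estimated correlation). The co-chaperone genes FKBP4 and STIP1 were at -0.53 ± 0.07 and -0.44 ± 0.06. NRF2 genes fell in 3 of 16 cases (5, adjusted p = 0.0011), TKT by 0.53 ± 0.07, with adjusted p = 0.0788 with an estimated correlation. Respiratory chain genes fell in 3 of 22 cases (5, adjusted p = 0.0155), NDUFA9 by 0.27 ± 0.05, with adjusted p = 0.0699 with an estimated correlation. G1/S genes fell in 6 of 28 cases (8, adjusted p = 0.0276), MCM3 by 0.32 ± 0.07, with adjusted p = 0.481 with an estimated correlation. The remaining lists were not called (adjusted p of 0.527 or more). Members changed in p53 targets (4 up and 0 down of 21, PMAIP1 at 0.55 ± 0.06; adjusted over the list alone 5 and 0), the ER unfolded protein response (2 and 4 of 17, EDEM1 at 0.99 ± 0.06 and SDF2L1 at -0.64 ± 0.09; 2 and 4). They also changed in immediate early genes (5 and 1 of 20, EGR1 at 0.69 ± 0.07; 5 and 1) and T-lineage genes (3 and 4 of 33, RAG2 at 0.69 ± 0.11 and CD7 at -0.51 ± 0.11; 3 and 4). Counts were 1 and 0 of 18 for cholesterol synthesis (0 and 0 adjusted over the list alone) and 0 and 1 of 24 for interferon-stimulated genes (ISG15 at -0.62 ± 0.07; 0 and 1). They were 2 and 1 of 16 for NF-kB targets (2 and 1) and 0 and 0 of 14 for markers of other blood cells (0 and 0). The median differed in sign from the mean for p53 targets (-0.03 and 0.03), immediate early genes (-0.09 and 0.09) and T-lineage genes. For cholesterol synthesis the mean of -0.01 differed from the direction of the test, which was up. In total 1846 genes changed, 980 higher and 866 lower, 18 and 8 of them by at least 1. That count was 915 without DMSO replicate 2, 996 without DMSO replicate 3, and 1124, 913 and 1117 without SAHM1 replicates 1, 2 and 3. It was 417 under quantile normalization, 1019 without probe sets of the suffix _x_at or _s_at, 52 with the 18S level as a covariate and 39 with the spike level added.

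**Figure D2:**
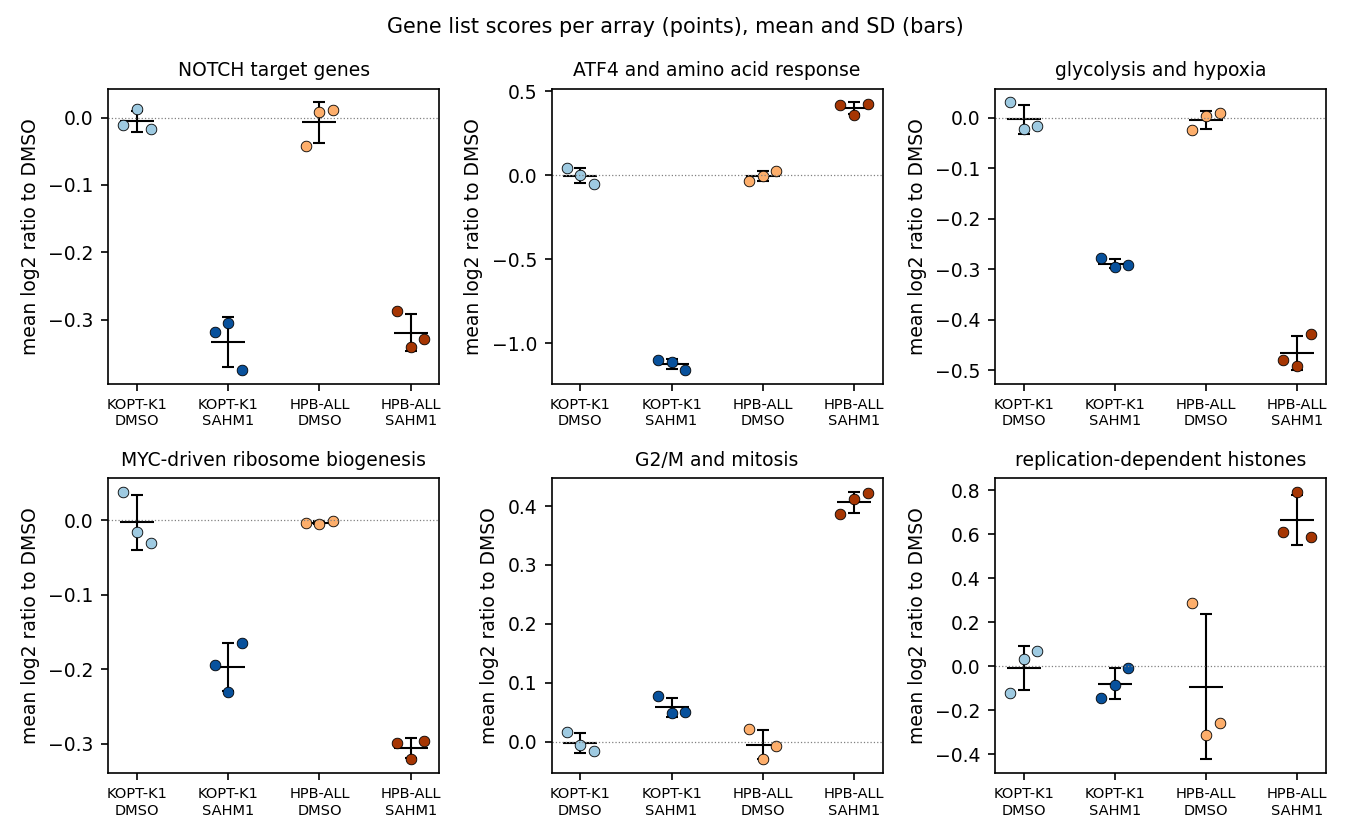
Mean log2 ratio to DMSO of the genes of 6 lists on each of the 12 arrays (points), with the mean and SD of each group of 3 arrays (bars). The ATF4 score differs between SAHM1 and DMSO by -1.12 in KOPT-K1 and by 0.40 in HPB-ALL, and the NOTCH target score by -0.33 and -0.31.

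**Figure D3:**
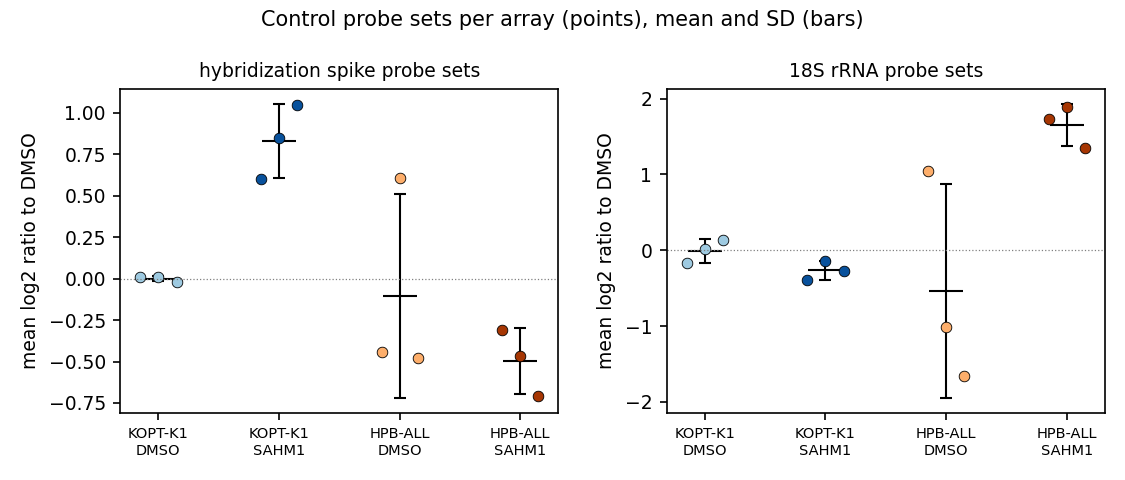
Mean log2 ratio to DMSO of 18 hybridization spike probe sets (left) and 3 probe sets for 18S ribosomal RNA (right) on each array (points), with the mean and SD of each group of 3 arrays (bars). Spikes are higher by 0.83 in KOPT-K1 with SAHM1, and 18S is higher by 2.19 in HPB-ALL with SAHM1, where DMSO replicate 1 stands at 1.05.

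The responses of the 2 lines differed in 3323 genes, 2253 of them with a higher value in HPB-ALL and 1070 with a lower one. ATF4 and amino acid genes stood apart by 1.53 on average, with 19 of 24 higher in HPB-ALL (22 adjusted over the list alone). Camera gave adjusted p = 3.91e-32, and adjusted p = 0.0011 with an estimated correlation. CHAC1 differed by 4.002 ± 0.18. Outside the list ANXA3 differed by 3.43 ± 0.24, H1-4 by 3.39 ± 0.67, TM6SF1 by 3.16 ± 0.17 and ASS1 by 3.14 ± 0.18. ASS1 fell by 1.69 ± 0.12 in KOPT-K1. Lower in HPB-ALL than in KOPT-K1 were the responses of ZNF528 (-2.16 ± 0.30), MEFV (-1.45 ± 0.21), LINC02504 (-1.41 ± 0.24), PLSCR4 (-1.37 ± 0.25) and LGMN (-1.26 ± 0.24). The zinc finger gene ZNF528 rose in KOPT-K1 and fell by 0.82 ± 0.21 in HPB-ALL. ZNF528, MEFV and LINC02504 each rested on 1 probe set with the suffix _x_at.

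G2/M genes responded more strongly in HPB-ALL, by 0.35 on average with 14 of 26 past the test (17 adjusted over the list alone). Camera gave adjusted p = 3.28e-09, and adjusted p = 0.0041 with an estimated correlation. T-lineage genes (0.20, adjusted p = 0.0081) and histones (0.83, adjusted p = 0.0043) had higher responses in HPB-ALL, each with adjusted p = 0.235 with an estimated correlation. The histone difference was 0.26 ± 0.14 with the 18S level as a covariate and 0.14 ± 0.16 with the spike level added, and that of H1-4 was 1.11 (adjusted p = 0.179) and 0.59 (adjusted p = 0.622). Lower responses in HPB-ALL were called for cholesterol synthesis (-0.24, adjusted p = 4.05e-04, and adjusted p = 0.0690 with an estimated correlation) and heat shock (-0.24, adjusted p = 0.0021, and adjusted p = 0.147 with an estimated correlation). The same held for glycolysis (-0.18, adjusted p = 0.0043, and adjusted p = 0.203 with an estimated correlation) and MYC-driven genes (-0.11, adjusted p = 0.0240, and adjusted p = 0.235 with an estimated correlation). The NOTCH target list differed by 0.02 on average (median -0.01, direction of the test down, adjusted p = 0.920). Of its 21 members 2 had a higher and 3 a lower response in HPB-ALL. The widest of these was in IL7R, the interleukin-7 receptor (1.14 ± 0.18, adjusted p = 0.0014), whose 2 probe sets fell in KOPT-K1 (-0.96 and -1.21) and stood at 0.04 and 0.07 in HPB-ALL. The growth factor receptor IGF1R differed by 0.57 ± 0.14 (3 of 5 probe sets called), having fallen in KOPT-K1 (-0.62 ± 0.10) but not passed the test in HPB-ALL (-0.05 ± 0.10). HEY1 (-0.64 ± 0.15), DTX1 (-0.44 ± 0.13, adjusted p = 0.0413) and SHQ1 (-0.27 ± 0.08) had lower responses in HPB-ALL. For this difference 1 of 2 probe sets was called for HEY1 (-0.98, the other at -0.30) and for SHQ1 (-0.32, the other at -0.21). With probe sets tested singly, the only 1 for DTX1 had adjusted p = 0.0632. IL7R, IGF1R and SHQ1 were chosen after their values were seen. The difference was 0.01 ± 0.13 for HES4 and 0.05 ± 0.10 for MYC. For the ER unfolded protein response the mean difference (0.10) and the median (-0.04) differed in sign. Immediate early genes did so in the mean of both lines (0.03 and -0.04). The count of 3323 became 211 under quantile normalization, 324 with the 18S level as a covariate and 68 with the spike level added.

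**Figure D4:**
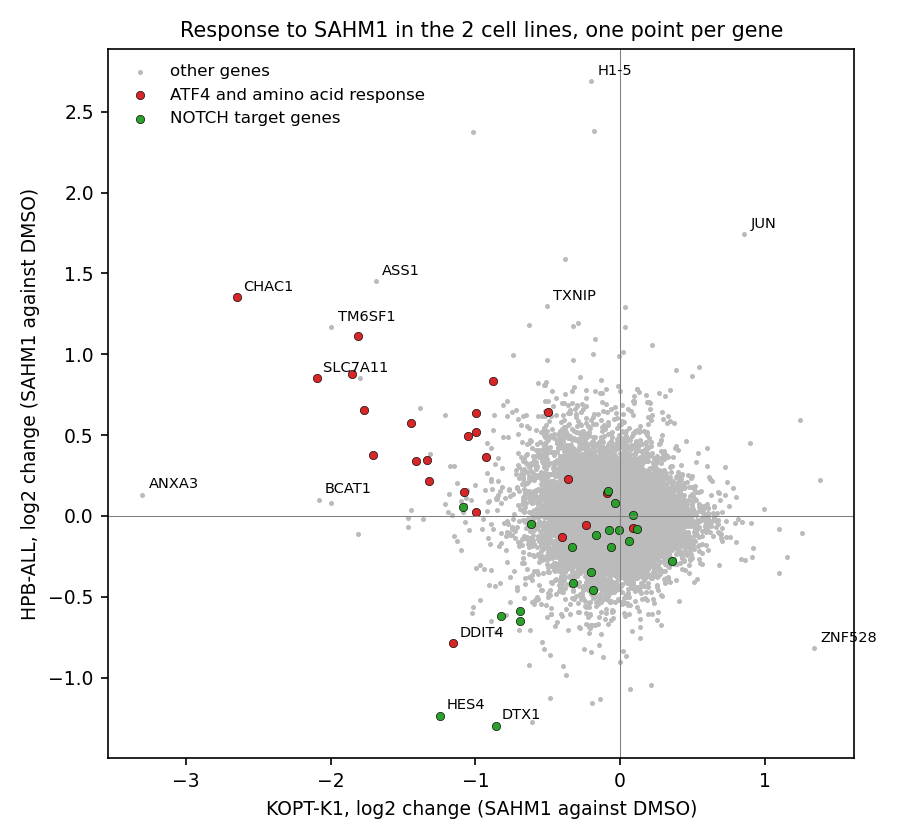
Log2 change with SAHM1 against DMSO in KOPT-K1 (horizontal) and HPB-ALL (vertical), 1 point per gene for 19775 genes, with the ATF4 list in red and NOTCH target genes in green. Most ATF4 genes lie at the upper left, CHAC1 at -2.65 and 1.36, while HES4 and DTX1 lie at the lower left.

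Across the 19775 genes the responses of the 2 lines had a Pearson r of -0.14 and a Spearman rho of -0.12. Genes are not independent replicates, so no p is given. Of 706 genes changed in both lines, 293 moved the same way and 413 the opposite way. Lower in both were 253 genes, against 114.1 for independent lists of these sizes, and 370 were lower in KOPT-K1 and higher in HPB-ALL, against 129.1. Higher in both were 40 genes, against 57.3, and 43 were higher in KOPT-K1 and lower in HPB-ALL, against 50.6. The lines share no control arrays, but both contrasts use the same residual variance of each gene. A gene with a small variance is more easily called in both lines. Overlaps above the number for independent lists are thus not by themselves a sign of related responses.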

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

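The tests of exchanged labels, of G1/S genes and of single histone genes below, and the use of spike and 18S levels as covariates, were chosen after the results they bear on or the data had been seen; the other tests were set out before their results were known.

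The test of the difference between lines singled out 3323 genes and 8 gene lists. The lists were ATF4 and amino acid response (1.53), histones (0.83), G2/M (0.35), T-lineage genes (0.20), MYC-driven ribosome biogenesis (-0.11), glycolysis (-0.18), cholesterol synthesis (-0.24) and heat shock (-0.24), each given as the HPB-ALL response minus the KOPT-K1 response. Only ATF4 and G2/M kept their call with an estimated correlation. The genes with the widest gaps were CHAC1 (4.002), ANXA3 (3.43), H1-4 (3.39), TM6SF1 (3.16), ASS1 (3.14), ZNF528 (-2.16), MEFV (-1.45), LINC02504 (-1.41), PLSCR4 (-1.37) and LGMN (-1.26). In control probe sets outside the gene comparisons, spikes were higher by 0.83 in KOPT-K1 with SAHM1 and 18S by 2.19 in HPB-ALL with SAHM1. Among 11721 probe sets that the annotation does not list, 1076 changed in KOPT-K1 and 181 in HPB-ALL.

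ATF4 and amino acid genes fell in KOPT-K1 and rose in HPB-ALL. With spike and 18S levels as covariates the list's difference between lines was 1.56 ± 0.07 (SE), against 1.53 before. The difference thus did not shrink with both levels in the fit. Spikes separate SAHM1 from DMSO in KOPT-K1, however, and 18S does so in HPB-ALL. Array-wide signal or RNA composition that goes with the treatment therefore cannot be told apart from it here. Exchanged treatment labels in 1 line would turn the NOTCH target score there, but that score was lower in both lines, at -0.31 in HPB-ALL. The cell line itself, and the state of the cultures such as nutrient supply or density, stay open and were not tested, and levels in DMSO cannot be compared on this scale.

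Histone genes rose in HPB-ALL, and the linker histones H1-2, H1-3, H1-4 and H1-5 also stood high on DMSO replicate 1, where 18S was high, while H2AC4, H2AC8 and H2BC3 did not. With the 18S level as a covariate the list's change was 0.25 ± 0.11 (SE), against 0.76 before, and the difference between lines 0.26 ± 0.14 (SE), against 0.83. The members differed: H1-3 went from 2.38 ± 0.52 to 0.08 ± 0.26, but H2AC6 from 0.92 ± 0.12 to 0.68 ± 0.19, H2BC5 from 0.48 ± 0.06 to 0.40 ± 0.10 and H2AC4 from 0.30 ± 0.13 to 0.33 ± 0.23, with the calls of H2AC6 and H2BC5 lost too (adjusted p = 0.231 and 0.181). Since 18S also separates SAHM1 from DMSO in this line, RNA composition and the treatment cannot be told apart for the list. A rise of over 0.1 in the G1/S score, set as the sign of more cells in S phase, was not seen: the score was at -0.0816 ± 0.03 (SE), and at -0.05 ± 0.04 (SE) with the 18S level as a covariate, though the list's own call as lower had adjusted p = 0.481 with an estimated correlation.

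The responses of the 2 lines correlated at -0.14 across genes. With spike and 18S levels as covariates r was -0.0682, between the -0.05 set for array-wide signal as the cause and the -0.1 set against it. Without HPB-ALL DMSO replicate 1 r was -0.17, further from 0, but its jackknife standard error over arrays of 0.083 reaches past -0.1. Of all arrays left out in turn, HPB-ALL DMSO replicate 2 moved r most, to -0.06. That error and that move keep the explanations open, so array-wide signal, single DMSO arrays of HPB-ALL and an opposition between the lines cannot be told apart here.

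Other divisions of the arrays were also run. Within a line 3 arrays against 3 allow 10 splits, too few for a share under 0.05: the real split called 3761 genes in KOPT-K1 and 1846 in HPB-ALL, 1 of 10 splits in each, and the highest of the others called 0. For the mean of both lines 2 of 100 drawn splits reached the real 2231, and the highest other, 3323, is the split that turns the labels of 1 line and thereby tests the difference between lines; the next was 1264. For that difference 1 of 100 splits reached 3323, and the highest other was 2231. For the lists 2 of 100 splits reached 37 calls, the real one and the split that turns the labels of 1 line. The latter exchanges the mean with the difference and so must give the same total. Each of these 3 shares was under the 0.05 set beforehand. Most other splits mix SAHM1 and DMSO arrays, which puts a real effect into the spread within groups. Their low counts, with a median of 0 genes for the mean and for the difference, follow partly from that. The splits also cannot separate SAHM1 from array-wide signal that goes with it.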

How the results depend on the processing

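The spike and 18S covariates, and the mean without _x_at and _s_at probe sets, which replaced the planned brightest of the remaining probe sets, are alternatives chosen after seeing the data; the other settings were planned. NOTCH target scores lay between -0.22 and -0.33 in all settings in which they were run. The exact p was 0.005 in each but the paired one and those with covariates, where no exact test was run. Of 242 calls of named genes 64 held in every alternative that gave the gene a value, and of 37 list calls 18 did. The setting without _x_at and _s_at probe sets gave values for only 171 of the 242, so the other calls could not be lost there. Fry, probe sets tested singly and the minimum log2 difference were kept as totals and did not enter these counts. Counts are given in the order KOPT-K1, HPB-ALL, mean and difference between lines, with main values of 3761, 1846, 2231 and 3323. Quantile normalization gave 136, 417, 294 and 211. It forces the same spread on treated and control arrays, whose log2 SD was 0.30 to 0.32 with SAHM1 against 0.12 to 0.13 with DMSO in KOPT-K1. DMSO arrays are ratios to their own mean, while SAHM1 arrays carry the response, so the ratio scale itself makes such a gap. The lower counts follow at least partly from that. Quantile normalization also moved the share of higher calls from 30.7% to 18.4% in KOPT-K1, from 53.1% to 33.1% in HPB-ALL and from 28.0% to 16.7% in the mean. Without _x_at and _s_at probe sets the first 3 counts were 2497, 1019 and 1239, with a share of higher calls of 63.3% in HPB-ALL, and HERPUD1 in KOPT-K1 turned to 0.0457 and TAL1 in HPB-ALL to 0.0685; the cause was not tested. Probe sets tested singly gave 6668 in KOPT-K1, 3648 in the mean and 5673 in the difference, as more features were tested. A minimum log2 difference of 1 left 58, 26, 5 and 161. List calls were 19 with estimated correlations, and 61 and 75 with fry's directional and mixed tests, which do not compare a list with other genes. With spike and 18S covariates the counts were 597, 39, 397 and 68, and H1-3 (-0.0095), ITCH (-0.0228) and DNAJC3 (-0.0088) turned in HPB-ALL. With 18S alone they were 3491, 52, 752 and 324. Under the 18S covariate the standard errors of genes in HPB-ALL grew by a median of 1.68-fold and the median size of called changes went from 0.35 to 0.28, with 99.7% of signs kept, so both a wider error and smaller sizes ended calls.

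Leaving out each array in turn gave 2528 to 3885 genes in KOPT-K1, 913 to 2012 in HPB-ALL, 1532 to 2202 in the mean, 2341 to 3369 in the difference, 34 to 38 list calls, and r from -0.17 (without HPB-ALL DMSO replicate 1) to -0.06 (without replicate 2). The HPB-ALL count moved by over 1.5 times without DMSO replicate 2 (915) or 3 (996), or without SAHM1 replicate 1 (1124), 2 (913) or 3 (1117). Same-numbered arrays did not deviate together (correlations of -0.01 to 0.07 in KOPT-K1 and -0.05 to 0.05 in HPB-ALL), and 2 of 3 and 1 of 3 DMSO arrays correlated best with their own number. With the replicate number as a block the counts were 3071, 1261, 1692 and 2616, with 36 list calls, and sign flips of the paired differences gave an exact p of 0.0312 for the NOTCH target score. Not run were the stricter filter on level, the brightest probe set per gene and every setting for the lines in DMSO, which need levels; no filter and the mean of all probe sets became the main setting. Signal over background is unknown on the ratio scale, so genes near background could not be left out.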

Other observations

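The gene families and tests below were chosen after other results had been seen, and families were built from gene symbols; the prediction for the synthetases was written before its test was run.

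In KOPT-K1 the cytosolic aminoacyl-tRNA synthetases outside the ATF4 list, which load amino acids onto tRNA for translation, fell in 9 of 13 cases with a mean of -0.55 (10 adjusted over the list alone, adjusted p = 3.66e-09, and adjusted p = 0.0150 with an estimated correlation). IARS1 was at -1.21 ± 0.05, EPRS1 at -1.07 ± 0.08 and SARS1 at -1.03 ± 0.06. In HPB-ALL 2 of these genes rose and 4 fell, with a mean of -0.05, TARS1 at 0.36 ± 0.07 and VARS1 at -0.86 ± 0.12. Mitochondrial synthetases were lower in both lines, by 0.18 in KOPT-K1 (6 of 15 lower, adjusted p = 0.0042) and by 0.17 in HPB-ALL (2 of 15, adjusted p = 0.0020), with adjusted p = 0.227 and adjusted p = 0.0829 with an estimated correlation.

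In HPB-ALL mitochondrial ribosomal proteins fell in 21 of 75 cases (mean -0.14), proteasome subunits in 9 of 34 (-0.13) and chaperonin subunits in 4 of 8 (-0.22), each with 0 higher and adjusted p = 0.0389 with an estimated correlation. Kinesins, the motor proteins of the spindle among them, rose in 7 of 38 cases with 0 lower (0.10, adjusted p = 0.0389 with an estimated correlation). KIF11, KIF20A and KIF23 are also in the G2/M list, so the 2 results are not separate. All family tests were run without covariates, and with the 18S level as a covariate only 52 genes were called in HPB-ALL. Cytosolic ribosomal proteins were not called in either line (0.02 and -0.03). Numbered ZNF zinc finger genes fell in 80 and rose in 13 of 425 cases in KOPT-K1 and rose in 28 and fell in 8 in HPB-ALL (adjusted p = 0.0032 and 5.73e-04), with adjusted p = 0.227 and adjusted p = 0.0829 with an estimated correlation.

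A hypothesis is that cytosolic synthetases outside the fixed list follow the ATF4 list while mitochondrial ones do not. The cytosolic minus mitochondrial score changed by -0.37 in KOPT-K1 and by 0.11 in HPB-ALL (exact permutation p = 0.10 in each, the smallest possible), a difference between lines of 0.48, and every SAHM1 array lay beyond every DMSO array of its line. The prediction had been a difference above 0.3, and the values met it for the contrast between the families. In HPB-ALL that contrast came from the mitochondrial family (-0.17) and not from a rise of the cytosolic one (-0.05), so there the cytosolic genes were not seen to follow the ATF4 list.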
